A study of Homo sapiens with 4 samples.

How the data were processed

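Total RNA of RPMI 8226 cells was sequenced 72 h after transfection with a control LNA (2 libraries) or an LNA against LINC01432 (2 libraries, 50 nM; the dose of the control LNA is not stated separately in the labels). Each library was placed in its group by its title, and the replicate numbers 1 and 2 come from the same titles. The labels disagree on how the RNA was selected: the series' design text names poly(A) selection, while the labels' protocols describe removal of ribosomal RNA with an RNase H method. The values go with removal of ribosomal RNA rather than poly(A) selection, since RNAs without poly(A) tails were abundant: 7SL RNA held 3.28% to 3.91% of a library's counts, histone genes 1.48% to 1.79% and SNORD3A 0.431% to 0.665%, while mitochondrial ribosomal RNA held 0.00162% to 0.0240%. RN7SK, another such RNA, was listed at 0 in each library.

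The deposited values are whole-number counts per gene, not normalized. Per the submitters' processing notes, STAR 2.7.11b, featureCounts 2.0.8 of Subread, Salmon 1.10.0 and bcl2fastq were used with the GRCh38 build; the notes give no role or order of these tools. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of a gene and its antisense or overlapping partner, or of near-identical copies, may therefore have been split or pooled. Some such genes are named as uncertain, but genes without that mark may be affected too. The table held 78932 gene rows, 92 rows of ERCC spike-in RNAs and 5 rows of transgene sequences. The last 2 kinds each took at most 3.44e-05% of a library and were left out of library sizes and tests. All columns belonged to the 4 libraries. Gene symbols came from a table of Ensembl IDs, which held 61481 of the gene IDs, and positions, gene types, GC content of the exons and exon overlap from GENCODE 29 on GRCh38, which held 57356 of them with 99.4% of the counts.

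The libraries held 20873393 to 29161298 gene counts. A count of 3, taken as the floor, was worth 0.103 to 0.144 CPM. None of the library pairs held identical values, and none agreed within counting noise, so no library was taken as deposited more than once. Each counted as 1 replicate, as the labels name them; this does not show that they came from separate cultures.

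Tests were run in R 4.3.3. The main test was the quasi-likelihood F test of edgeR 4.0.16 on the counts, with TMM normalization, filterByExpr (minimum count 10, minimum total 15) and group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Standard errors of log2 fold changes were derived from the F statistic. CPM were computed with TMM-scaled library sizes and are given as mean ± SD over the 2 libraries of a group. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so significance rests on the spread that edgeR pools across genes (biological coefficient of variation 7.13%). The 28 gene lists, the groups, the main test and most alternatives were fixed before the data were examined. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The lists were pro-apoptotic, anti-apoptotic, DNA replication, mitotic, p53 target, ATF4, ER chaperone and secretory, type I interferon, NF-kB, plasma cell and myeloma, MAF target, B cell, MYC target and ribosome biogenesis, cytosolic ribosomal protein, proteasome, heat shock, cholesterol synthesis, hypoxia and glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, histone, structured RNA, speckle and paraspeckle, and CELF and splicing genes, and markers of T and NK, myeloid, epithelial, and fibroblast and endothelial cells.

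Genes were named by a rule: LINC01432 and CELF2; the 12 largest rises and the 12 largest falls among called genes with a symbol, a mean of at least 5 CPM and both LINC01432 LNA libraries beyond both controls; and up to 4 members of each list with the smallest p, of which the text names fewer for several lists. Other genes, and the further lists of the closing section, were chosen after their values were seen. Alternatives were another normalization (DESeq2's median of ratios, or library totals only), other filters, leaving out each library, the replicate number as a block, fits without mitochondrial, immunoglobulin and structured RNA genes, the DESeq2 1.42.0 Wald test, limma-voom, stricter thresholds and other list tests. After the data were seen, corrections for GC content, for GC content and exon length, and for GC content with the replicate block were added. They subtract a lowess trend (span 0.3) of each library's log2 CPM on the property. Figures were drawn with matplotlib in Python.

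The edgeR step was tested on simulated counts for 18155 genes with the means and library sizes of these libraries and 200 genes changed. For the comparison of LINC01432 LNA with control LNA it recovered 77.6% of the genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 29 false calls (13.6% of the calls, more than the threshold aims at). With a simulated GC trend there were 5319 false calls without the GC correction and 10 with it (18183 genes run). The simulated trend was linear and alike in both LINC01432 LNA libraries. It was also steeper than the trend of the data, a log2 fold change of 0.19 per 10 GC percent. These numbers of false calls therefore do not carry over to the measured libraries. The list test recovered a changed list made of raised genes, and 3 of 100 random lists had an unadjusted p under 0.05. The simulated genes varied independently, so this does not test the preset correlation on lists whose genes move together. The estimated correlation of the interferon list was 0.39.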

Results

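Gene expression was measured by RNA-seq in RPMI 8226, an established human multiple myeloma cell line, 72 h after transfection with locked nucleic acid (LNA) antisense oligonucleotides. LNA oligonucleotides are short modified DNA strands that lower the level of the RNA they are complementary to. There were 2 groups of 2 libraries: cells given a control LNA and cells given an LNA against LINC01432, a long intergenic noncoding RNA, at 50 nM. The deposited table held 29161298 and 24493148 gene counts for control LNA libraries 1 and 2, and 20873393 and 26185342 for LINC01432 LNA libraries 1 and 2. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The counts of the control pair differed by 3.85 times the variance expected from counting alone, those of the LINC01432 LNA pair by 12.4 times, and pairs across groups by 18.2 to 35.9 times.

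The first question was whether the targeted RNA was lower. LINC01432 (ENSG00000234435, a lincRNA gene on chromosome 20 from 22054090 to 22074654 in GRCh38) had 598 and 440 counts in the control LNA libraries and 193 and 250 in the LINC01432 LNA libraries. Its level fell from 19.2 ± 1.84 to 9.45 ± 0.642 CPM (counts scaled to library size; SD, n = 2 libraries each), a log2 fold change of -1.02 with a standard error of 0.11 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000228). About 49.2% of the control level thus remained. CELF2 (ENSG00000048740, chromosome 10), an RNA-binding regulator of splicing, was measured at 123 ± 0.524 CPM with control LNA and 105 ± 3.59 CPM with LINC01432 LNA. Its log2 fold change of -0.23 did not pass (edgeR adjusted p = 0.0787). Without LINC01432 LNA library 1 it was -0.28 and without library 2 it was -0.21, and both fits called it, with the lone library assumed to vary like the control pair.

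**Figure D1:**
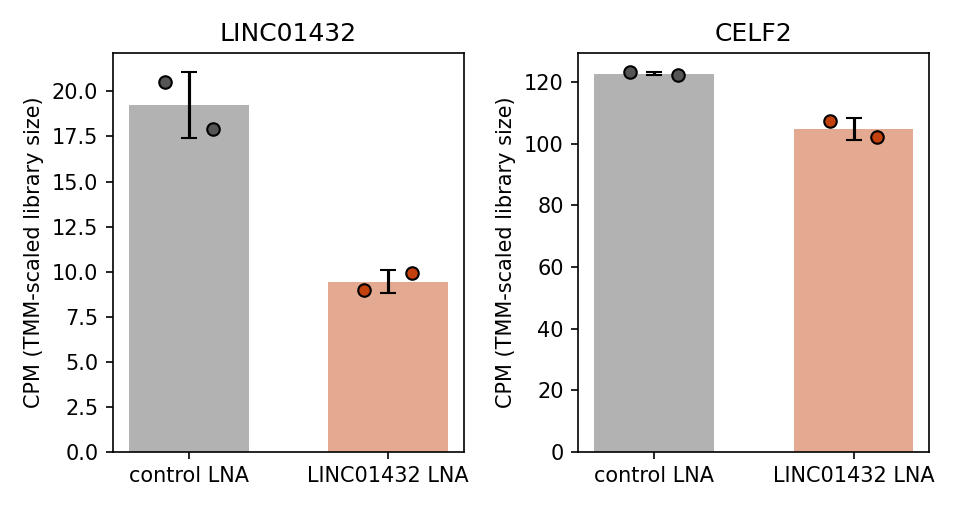
Level of LINC01432 and CELF2 in CPM (vertical axis, from 0) in the control LNA and LINC01432 LNA groups; points are the 2 libraries of each group, bars their mean and whiskers the SD. LINC01432 lies at 19.2 and 9.45 CPM in the 2 groups, and CELF2 at 123 and 105 CPM.

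The second question was which other genes differed between the groups. Type I interferon response and NF-kB target genes were higher with LINC01432 LNA, and genes of ER chaperones and secretion (ER, endoplasmic reticulum) were lower, by a test with a preset correlation between genes. With an estimated correlation none of these 3 lists was called (adjusted p = 0.794 for each). That form of camera rests on 2 residual degrees of freedom, so it could call few lists whatever their correlation. For the CELF and splicing list the estimated correlation was -0.03, below the preset 0.01, yet the camera p rose from 0.00549 to 0.0870. The interferon, NF-kB and ER lists, however, had estimated correlations of 0.39, 0.11 and 0.26, far above the preset value. For them the correlation itself also weakened the evidence, and their p-values at the preset value may be too small. Neither a call at the preset correlation nor a call lost with the estimated one thus decides whether a list changed. Of 18680 genes tested, 2218 changed (edgeR, adjusted p under 0.05): 1401 were higher and 817 lower with LINC01432 LNA, so that 63.2% of the changed genes were higher. Changes of at least 2-fold were more often upward, with 354 genes higher and 34 lower. The 2218 genes all had both LINC01432 LNA libraries on the same side of both control libraries. That held for 54.1% of the tested genes, where chance gives 33.3%. In the LINC01432 LNA libraries the level of a gene followed its GC content: the median log2 fold change was -0.14 in the lowest decile of genes by GC and 0.37 in the highest, and 600 of the 1401 higher genes lay in the highest decile. With a correction for GC content, added after the data were seen, 1858 genes changed, 970 higher and 888 lower, or 52.2% higher. Of these, 1385 had been called in the same direction and 6 in the opposite direction. The count was lower without either control library and higher without either LINC01432 LNA library. A fit with 1 library left in a group takes its spread from the other pair. The control pair varied less than the LINC01432 LNA pair (3.85 against 12.4 times the counting variance). These counts therefore do not show that any single library made the changes.

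**Figure D2:**
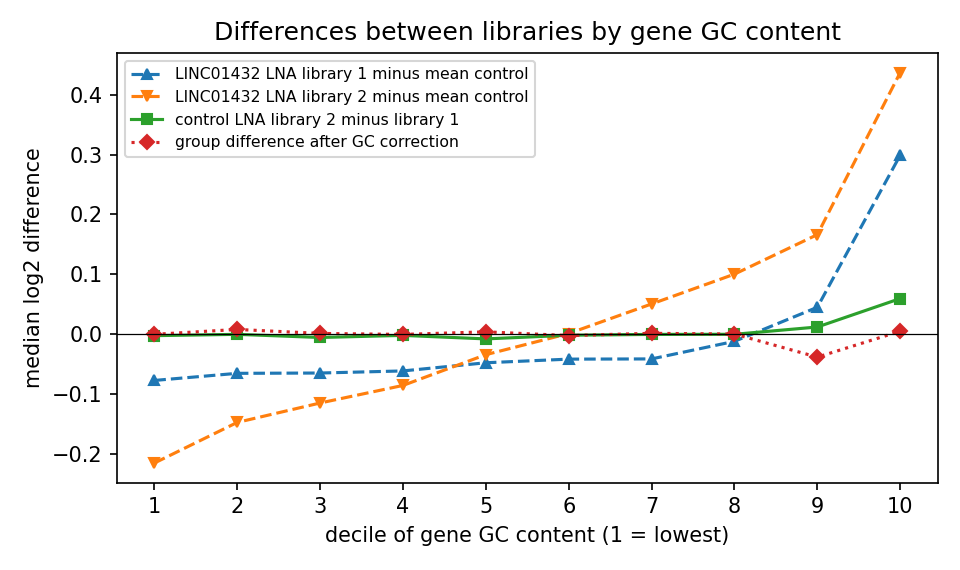
Median log2 difference (vertical axis) over deciles of 13755 genes ordered by GC content (horizontal axis, lowest to highest), for each LINC01432 LNA library against the control mean, for control library 2 against control library 1, and for the group difference after GC correction. In the highest decile the LINC01432 LNA libraries lie at 0.30 and 0.44, the control pair differs by 0.06, and the corrected difference is 0.00.

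The 12 named genes with the largest rises included several known to be induced by interferons. CXCL10 and CXCL9, chemokines that attract T cells, rose from 7.95 ± 0.749 to 93.6 ± 16.6 CPM (11.8-fold; SD, n = 2) and from 4.84 ± 1.11 to 26.0 ± 2.65 CPM (5.42-fold). The guanylate-binding protein genes GBP4 and GBP1 rose 6.35-fold and 4.74-fold, and the antiviral gene RSAD2 rose 4.74-fold. IL4I1, a secreted amino acid oxidase, rose 5.85-fold. LRRC26, NPW and CCDC85B rose 8.82-fold, 8.16-fold and 4.34-fold. These last 3 genes have GC contents of 74.7%, 72.6% and 67.7%, and their log2 fold changes of 3.14, 3.03 and 2.12 were 2.08, 2.10 and 1.51 after GC correction, still called. Without LINC01432 LNA library 2 that of NPW was 2.42. Of LRRC26, 27.9% of the exonic bases overlap another gene. Counts of the other 3 cannot be assigned with certainty. MRPL12 rose 9.15-fold but 68.2% of its exonic bases overlap another gene, CHCHD2P9 (5.36-fold) is a processed pseudogene, and RNA5-8SN2 (15.4-fold) is 1 of several near-identical 5.8S ribosomal RNA copies, with a log2 fold change of 4.64 instead of 3.95 without control library 2. All 12 had an edgeR adjusted p of 0.000221 or less.

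The largest falls were smaller than the largest rises. NCAM1 (CD56), an adhesion molecule found on many myeloma cells, fell 2.53-fold from 27.2 ± 1.72 to 10.8 ± 2.06 CPM (SD, n = 2). BLNK, the adaptor that couples the B cell receptor to its downstream kinases, fell 2.02-fold from 44.0 ± 1.76 to 21.8 ± 1.02 CPM. ZWILCH, a kinetochore component, fell 2.05-fold, and FTO, an RNA demethylase, fell 1.97-fold. The adhesion receptor gene ADGRG1 fell 2.12-fold, the ion channel genes SCN9A and KCNQ5 fell 1.92-fold and 1.84-fold, and MBIP, RNF144B and VPS33A fell 1.98-fold, 1.87-fold and 1.82-fold. RAPH1 fell 2.34-fold, but 75.8% of its exonic bases overlap ABI2, and 21.5% of those of VPS33A overlap another gene. LINC01432 itself ranked among these 12 genes. Their edgeR adjusted p lay between 3.14e-05 and 0.00219, and GC correction left all 12 called.

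Genes of the type I interferon response rose together. Of the 45 members tested, 37 rose, 0 fell and 8 did not pass, with a median log2 fold change of 0.68 (41 rose when adjusted over the list alone). IFIT2 rose from 6.25 ± 0.439 to 24.5 ± 2.34 CPM and IFIT3 from 78.7 ± 13.8 to 270 ± 36.6 CPM (SD, n = 2), both members of an antiviral gene family. IRF7, a transcription factor of interferon genes, rose 2.87-fold and IFIT1 rose 2.57-fold. After GC correction the log2 fold change of IRF7 was 0.96 instead of 1.52, still called. The list was called by camera with a preset correlation of 0.01 (adjusted p = 7.27e-18) and not with an estimated correlation (adjusted p = 0.794). NF-kB target genes rose as well: 17 of 26 tested members rose, 0 fell and 9 did not pass, with a median of 0.77 (21 rose when adjusted over the list alone). Besides CXCL10, the IκB family genes NFKBIZ and NFKBIA rose 3.88-fold and 1.91-fold, and RELB, a subunit of NF-kB, rose 2.94-fold. The camera adjusted p was 2.32e-10, and with an estimated correlation adjusted p = 0.794. After GC correction 38 interferon genes and 18 NF-kB genes rose, with medians of 0.79 and 0.75.

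**Figure D3:**
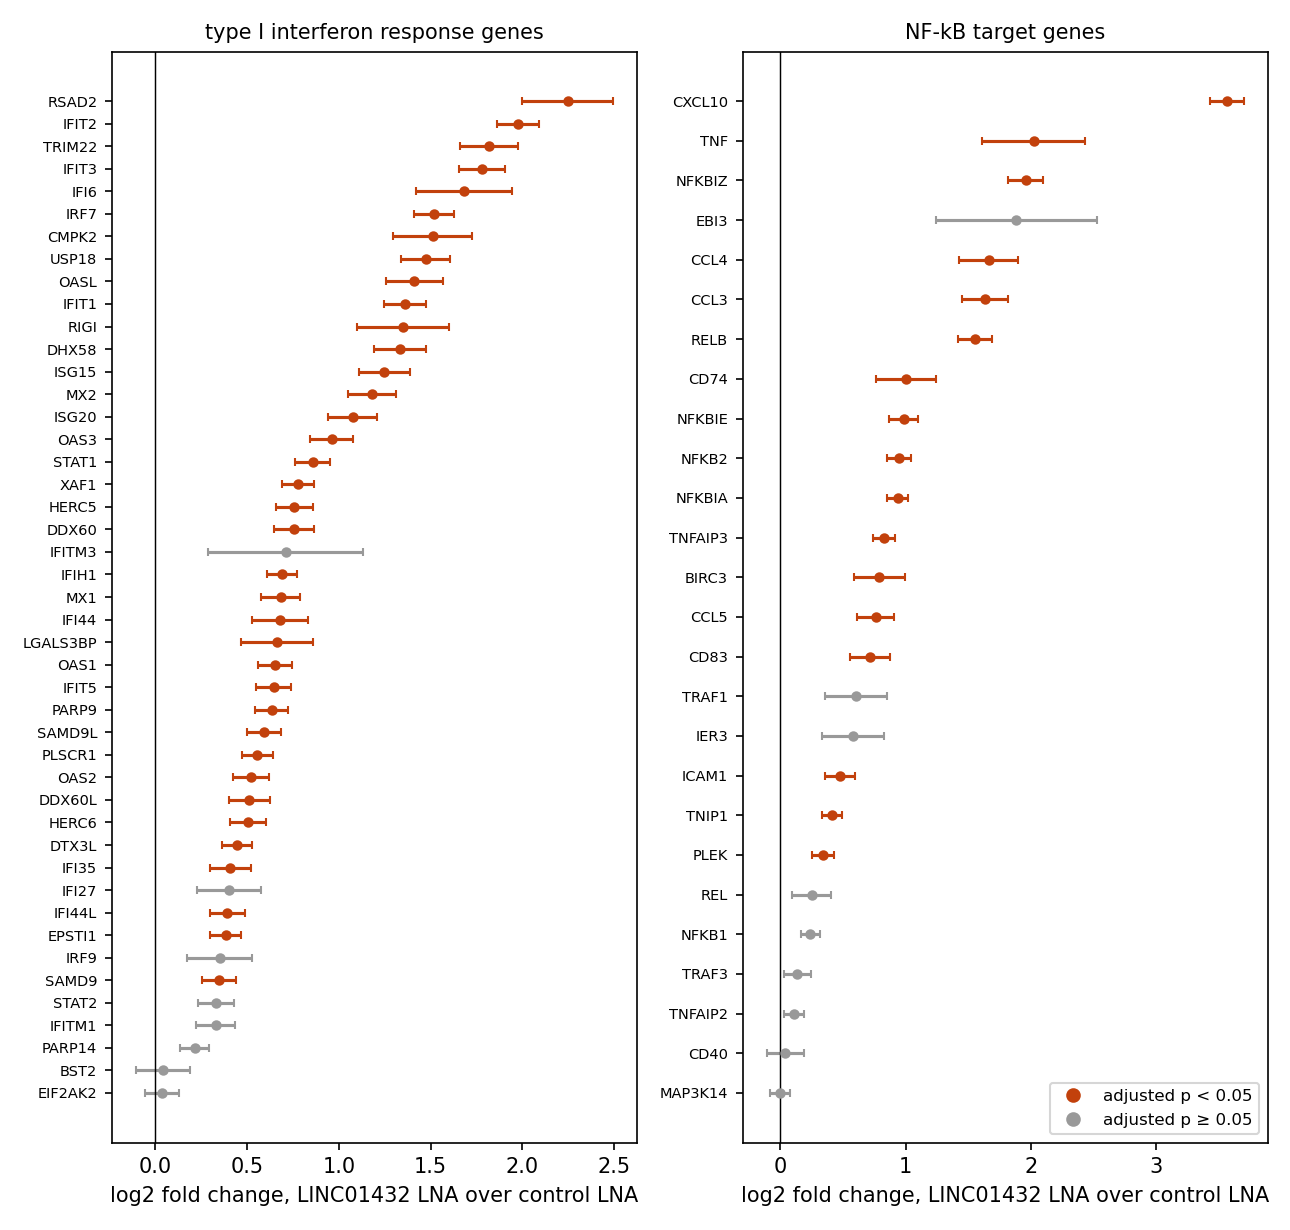
Log2 fold change of LINC01432 LNA over control LNA (horizontal axis) for each tested member of the type I interferon list (45 genes) and the NF-kB list (26 genes); whiskers are standard errors, and coloured points passed an adjusted p of 0.05. The 37 and 17 coloured genes all lie above 0.

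Genes of cell death changed in both pro-survival and pro-death groups. Of 29 pro-apoptotic genes tested, 9 rose, 0 fell and 20 did not pass, with a median log2 fold change of 0.18 (12 rose and 1 fell when adjusted over the list alone). TNFSF10, the gene of the death ligand TRAIL, rose from 8.81 ± 1.14 to 27.7 ± 3.81 CPM (3.16-fold; SD, n = 2). BAD rose 3.30-fold, ENDOG 2.87-fold and FADD 2.44-fold, but 23.7%, 39.2% and 54.9% of their exonic bases overlap other genes, and the strand used in counting is not given. After GC correction the log2 fold change of ENDOG was 0.91 instead of 1.52, still called. The list was called by camera (adjusted p = 0.00501), but not with an estimated correlation (adjusted p = 0.794). Without LINC01432 LNA library 2 its median was 0.07 and its call was lost (adjusted p = 0.0669). Of 10 anti-apoptotic genes, 4 rose and 0 fell: CFLAR, BCL2, BIRC3 and MCL1 rose 1.36-fold, 1.29-fold, 1.73-fold and 1.21-fold (median 0.05; 4 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.788). CFLAR, BCL2 and MCL1 were not called without control library 1 (log2 fold changes 0.45, 0.30 and 0.23) or without control library 2 (0.42, 0.40 and 0.29). MCL1 was also not called by DESeq2 (adjusted p = 0.0914), with the median of ratios as scaling (0.0553) or without a filter on low counts (0.0576), nor BIRC3 with library totals as the only scaling (adjusted p = 0.0657). Without LINC01432 LNA library 1 the log2 fold change of BIRC3 was 0.40 instead of 0.79, still called. Of 25 p53 target genes, 9 rose and 3 fell, including SESN2 (1.67-fold), BBC3 (2.38-fold) and GADD45A (1.55-fold). Their median was -0.01 while their mean of 0.13 and the direction of camera were positive (adjusted p = 0.605; 9 rose and 4 fell when adjusted over the list alone).

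Among targets of ATF4, the transcription factor of the integrated stress response, 11 of 33 rose, 2 fell and 20 did not pass, with a median log2 fold change of 0.16 (11 rose and 2 fell when adjusted over the list alone). SLC3A2, part of amino acid transporters, rose from 357 ± 0.586 to 872 ± 122 CPM (2.44-fold; SD, n = 2). CEBPB, ATF3 and CHAC1 rose 2.09-fold, 2.14-fold and 2.15-fold. After GC correction the log2 fold change of CEBPB was 0.55 instead of 1.06, still called. The camera adjusted p was 0.0357, and with an estimated correlation adjusted p = 0.988. The call was also lost without control library 1 (median 0.05, adjusted p = 0.240) and without LINC01432 LNA library 2 (median 0.04, adjusted p = 0.219). Genes of ER chaperones and secretion moved the other way: of 36 tested, 0 rose, 9 fell and 27 did not pass, with a median of -0.18 (1 rose and 12 fell when adjusted over the list alone). TXNDC11 fell 1.40-fold, SSR1 1.35-fold, and HSP90B1 and PDIA3, chaperones of secreted proteins, 1.30-fold each. The list was called by camera (adjusted p = 6.29e-06), not with an estimated correlation (adjusted p = 0.794), and after GC correction 6 of its genes fell. Without either control library, none of these 4 genes was called (adjusted p = 0.0767 to 0.352), with log2 fold changes between -0.51 and -0.36, against -0.48 to -0.38 with all libraries.

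Plasma cell and myeloma genes split: 2 of 30 rose and 5 fell, with a median log2 fold change of -0.11 (camera adjusted p = 0.117; 3 rose and 6 fell when adjusted over the list alone). Without LINC01432 LNA library 2 the list was called as lower (adjusted p = 0.0124). The surface antigens moved in both directions. CD38 rose from 84.6 ± 5.47 to 140 ± 11.8 CPM (SD, n = 2), whereas TNFRSF17, which encodes BCMA, fell from 88.4 ± 1.79 to 61.1 ± 3.29 CPM and GPRC5D from 35.4 ± 0.573 to 24.5 ± 2.58 CPM. Of 15 targets of the transcription factor MAF, 2 rose and 4 fell (median -0.12, camera adjusted p = 0.252; 3 rose and 5 fell when adjusted over the list alone). DEPTOR, an inhibitor of mTOR, fell from 205 ± 1.32 to 125 ± 3.69 CPM. Of 19 B cell genes, 7 rose and 4 fell (median 0.07, camera adjusted p = 0.788; 8 rose and 8 fell when adjusted over the list alone). CIITA, the activator of HLA class II genes, rose 2.93-fold, although 23.4% of its exonic bases overlap DEXI, and HLA-DRA and HLA-DPA1 rose 2.39-fold and 3.62-fold, while BLNK fell.

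**Figure D4:**
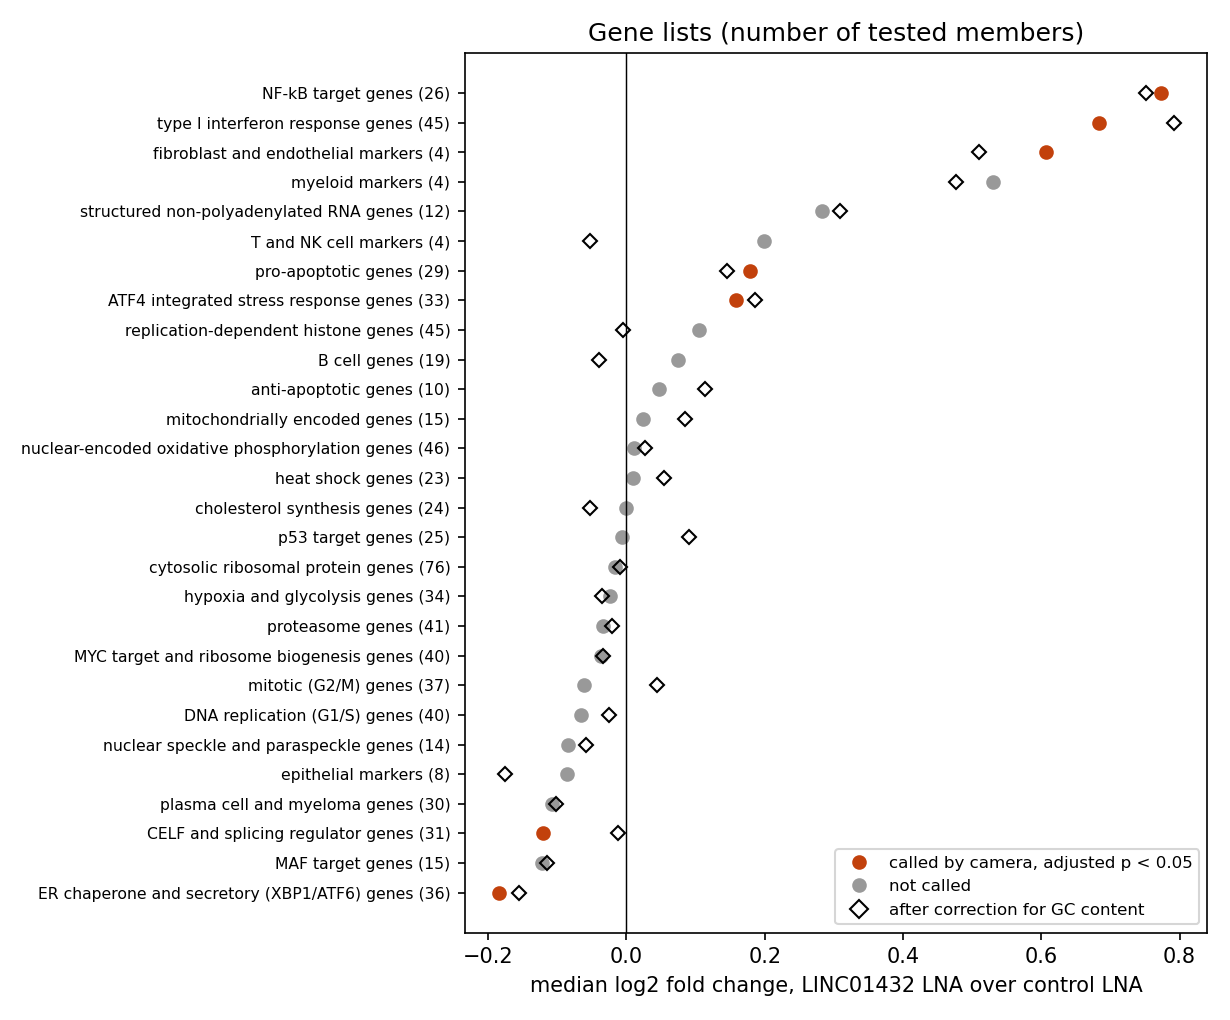
Median log2 fold change of LINC01432 LNA over control LNA (horizontal axis) for the tested members of the 28 gene lists, whose numbers stand in brackets; coloured circles were called by camera with a preset correlation, grey circles were not, and open diamonds show the median after GC correction. The NF-kB and interferon lists lie highest at 0.77 and 0.68, and the ER chaperone list lowest at -0.18.

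Genes of growth and metabolism mostly did not pass, and none of these lists was called with all 4 libraries. Leaving out a library changed this at the preset correlation. Without LINC01432 LNA library 2 the ribosomal protein, proteasome, mitochondrially encoded, nuclear oxidative phosphorylation and MYC target lists were called as lower. Without LINC01432 LNA library 1 the mitochondrially encoded list was called as higher. Such a fit takes its spread from the control pair. With all 4 libraries the estimated correlations of these lists were 0.48, 0.49, 0.91, 0.65 and 0.20, far above the preset 0.01. These calls therefore do not show that the lists changed. Of 40 DNA replication genes, 4 rose and 3 fell (median -0.07, camera adjusted p = 0.355; the same numbers when adjusted over the list alone). CDT1 rose 1.58-fold, but after GC correction its log2 fold change was 0.21 instead of 0.66 and was not called, nor was it called without control library 1 (0.58). Of 37 mitotic genes, 1 rose and 2 fell (median -0.06, adjusted p = 0.329; 1 and 0 when adjusted over the list alone); CCNA2 rose 1.41-fold but was not called without control library 1 (0.43). Of 40 MYC target and ribosome biogenesis genes, 1 rose and 1 fell (median -0.04, adjusted p = 0.329; 0 and 0 when adjusted over the list alone). Of 76 ribosomal protein genes, 4 rose and 1 fell (median -0.02, adjusted p = 0.355; 3 and 1 when adjusted over the list alone), with RPLP2 2.04-fold higher. Of 41 proteasome genes, 3 rose and 3 fell (median -0.03, adjusted p = 0.353; the same numbers when adjusted over the list alone). Of 23 heat shock genes, 2 rose and 0 fell (0.01, adjusted p = 0.985). Of 24 cholesterol synthesis genes, 3 rose and 2 fell (-0.00, adjusted p = 0.866; 4 and 2 when adjusted over the list alone). Of 34 hypoxia and glycolysis genes, 4 rose and 2 fell (-0.02, adjusted p = 0.856; 4 and 3 when adjusted over the list alone), among them EGLN1, 1.63-fold higher, and NDRG1, 0.683 times its control level. Of 46 nuclear oxidative phosphorylation genes, 2 rose and 1 fell (0.01, adjusted p = 0.897), and of 15 mitochondrially encoded genes 0 passed (0.02, adjusted p = 0.985). For these last 2 lists and the heat shock list the numbers adjusted over the list alone were the same. The ribosomal protein, cholesterol and hypoxia lists had a positive mean (0.01, 0.03 and 0.03) beside a negative median and a downward camera direction. The heat shock, nuclear oxidative phosphorylation and mitochondrially encoded lists had a positive median and mean (means 0.04, 0.04 and 0.22) beside a downward camera direction.

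Of 45 replication-dependent histone genes, 8 rose and 2 fell (median 0.10, camera adjusted p = 0.329; 11 and 4 when adjusted over the list alone); H2AC16 and H2AC4 rose 1.89-fold and 1.53-fold, and after GC correction the median was -0.01 and the log2 fold change of H2AC16 was 0.55 instead of 0.92, still called. Of 12 structured RNAs without poly(A) tails, the spliceosomal RNAs RNU4-1 and RNU4-2 rose 1.73-fold and 1.51-fold and 0 fell (median 0.28, adjusted p = 0.117; 2 and 0 when adjusted over the list alone). At the preset correlation the list was called as higher without control library 1, while its estimated correlation with all libraries was 0.15. RNU4-2 was not called without control library 1 (0.57) or by DESeq2 (0.56). Of 14 speckle and paraspeckle genes, SRRM1 fell to 0.814 of its control level and 0 rose (median -0.08, adjusted p = 0.355; 0 and 1 when adjusted over the list alone). SRRM1 was not called without control library 1 (-0.33) or 2 (-0.30). Of 31 CELF and other splicing regulator genes, PTBP3 fell to 0.803 of its control level and 0 rose (median -0.12; 0 and 0 when adjusted over the list alone). PTBP3 was not called without control library 1 (-0.39) or 2 (-0.27), after GC correction (-0.17) or with library totals as the only scaling (-0.32, adjusted p = 0.0734). The camera adjusted p of this list was 0.0256, and with an estimated correlation adjusted p = 0.794. After GC correction its median was -0.01 (adjusted p = 0.672), and without each of control library 1, control library 2 and LINC01432 LNA library 1 its median was -0.14, -0.11 and -0.10 with an adjusted p of 0.0834, 0.0664 and 0.0556. Without a filter on low counts the adjusted p was 0.0611 at a median of -0.12.

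Few of the T and NK cell, myeloid, and fibroblast and endothelial markers had enough counts to be tested. Of 16 T and NK cell markers 4 were tested, and CD8B fell to 0.789 of its control level and 0 rose (median 0.20, camera adjusted p = 0.985). CD8B was not called without control library 1 (-0.35) or 2 (-0.36). Of 14 myeloid markers 4 were tested, and CST3 rose 2.02-fold (median of the list 0.53, adjusted p = 0.131). At the preset correlation the list was called as higher without control library 2 and without LINC01432 LNA library 1. Its estimated correlation with all libraries was 0.74, so these calls do not show that the list changed. CST3 had a log2 fold change of 0.26 and no call without LINC01432 LNA library 2. It was also not called by DESeq2 (adjusted p = 0.402) or limma-voom (0.0849), with library totals (0.0699) or the median of ratios (0.0566) as scaling, with the filter at 1 CPM (0.0527) or after GC correction (0.0556). Of 12 epithelial markers 8 were tested and 0 passed (median -0.09, adjusted p = 0.329). Of 14 fibroblast and endothelial markers 4 were tested, and FN1 rose from 318 ± 11.3 to 596 ± 51.8 CPM and COL1A1 from 2.13 ± 0.442 to 3.82 ± 0.530 CPM (SD, n = 2). COL1A1 was not called without control library 1 (0.63), by DESeq2 (0.82) or after GC correction (0.65). This list was called by camera (median 0.61, adjusted p = 0.0250), not with an estimated correlation (adjusted p = 0.794) and not after GC correction (median 0.51, adjusted p = 0.0925). It was also not called without control library 2, LINC01432 LNA library 1 or LINC01432 LNA library 2, with medians of 0.45, 0.44 and 0.26. Adjusted over the list alone, 1 T and NK cell marker fell, 1 myeloid marker rose, 0 epithelial markers passed and 3 fibroblast and endothelial markers rose.

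Long noncoding RNAs can act on neighbouring genes, so genes near LINC01432 were examined. Within 1000 kb, 8 genes were tested and 0 passed by edgeR, over all genes or over the window alone (lowest adjusted p over the window 0.139); 2 of the 8 had an unadjusted p under 0.05. These were RPL41P1, a pseudogene measured at 2.01 ± 0.417 CPM with control LNA and 1.25 ± 0.204 CPM with LINC01432 LNA, and PAX1, at 1.27 ± 0.285 and 1.97 ± 0.0773 CPM (SD, n = 2). XRN2, an RNA exonuclease gene in the window, had a log2 fold change of -0.07. Within 250 kb, 0 genes had enough counts to be tested.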

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

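Rows outside the gene table's main measurement held a few counts. The 92 rows of ERCC spike-in RNAs, synthetic RNAs sometimes added as standards, had 9 counts in LINC01432 LNA library 2 and 3 in library 1, against 3 and 1 in the control LNA libraries. The 5 transgene rows had 2 counts in LINC01432 LNA library 2 and 1 in library 1, against 0 and 0 in the controls. The ERCC rows lie above the control level only in the sense of a highest count, while for the transgene rows both LINC01432 LNA libraries lie above both controls. The numbers are at or near the floor of 3 counts except for the 9, and no explanation was tested.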

How the results depend on the processing

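The GC corrections were chosen after the data were seen. The fall of LINC01432 kept its direction and its call under all 15 alternatives (log2 fold change -1.13 to -0.94; adjusted p at most 0.000847). In the main fit 0 genes were called within 1000 kb of it. Within 250 kb 0 genes could be tested, so the smaller window gives no result. The number of changed genes depended on single libraries: leaving out 1 gave 766 to 5228 genes, 566 to 2637 higher and 200 to 2591 lower, where the lone library is assumed to vary like the other pair; which pair then sets the spread changes by construction. It was 1400 with DESeq2 (783 higher), 1000 at an adjusted p under 0.01 (729 higher, 271 lower) and 388 at 2-fold or more (354 and 34). The replicate numbers share only a number: same-numbered deviations correlated at 0.135 over 18680 genes. With the replicate block 3862 genes were called (2245 higher, 1617 lower), and with GC correction and the replicate block 3735 (1813 lower) and 4 lists instead of 7. The block also called CELF2 (-0.23, adjusted p = 0.0280) and did not call the ATF4 list (median 0.15, adjusted p = 0.0605), nor did the block with GC correction (0.18, adjusted p = 0.0642); the cause was not tested. With an estimated correlation 0 lists were called and with fry, which tests a list's own genes, 0 by direction (adjusted p = 0.0643 to 0.230 for the 7 lists called with the preset correlation). The test with an estimated correlation has 2 residual degrees of freedom, so few lists could pass it. Most of these lists also had estimated correlations above the preset value, up to 0.39 for the interferon list, which weakened their evidence as well. Leaving out libraries gave 6 to 10 lists. The median of the CELF list turned to 0.01 with GC and exon length correction. Among lists that were not called, GC correction turned the medians of the T and NK (0.20 to -0.05), B cell (0.07 to -0.04), histone (0.10 to -0.01), mitotic (-0.06 to 0.04) and p53 lists (-0.01 to 0.09).

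No named gene reversed with another normalization or filter. Of the genes picked from the lists, BOP1 and HSF1 (log2 fold changes -0.18 and -0.17), CD7 (-0.13) and CD3E (0.026) reversed with GC correction. With GC and exon length correction BOP1, HSF1, CD7, CD3E and ADRM1 were at -0.18, -0.16, -0.14, 0.015 and -0.0083. With GC correction and the replicate block BOP1, HSF1, CD7, CD3E and COL6A1 were at -0.17, -0.17, -0.15, 0.047 and -0.0011, and BOP1 and HSF1 were called (adjusted p = 0.0237 and 0.0278). CD3E also reversed with the replicate block (0.012) and limma-voom (0.033). Without 1 library CD3E lay between -0.35 and 0.48, MT-ND4L between -0.32 and 0.80 (called as lower without LINC01432 LNA library 2, adjusted p = 2.91e-07) and CLDN4 between -0.052 and 0.31. B2M, which was not called, lay between -0.072 and 0.31. Of these genes ADRM1 alone had been called with all libraries and no correction; the corrections remove GC trends by construction, and the other causes were not tested. Among the genes named by the rule fixed beforehand, 15 lost their call with GC correction and 9 with DESeq2. More of them lost it without a control library than without a LINC01432 LNA library. A fit with 1 library left in a group takes its spread from the other pair, and the LINC01432 LNA pair varied more. Calls lost without a control library therefore do not show that the gene depended on that library. Depth limits genes under about 1 CPM.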

Other observations

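The tests on gene body length, within-group GC trends, matched lists, left-out libraries, LNA designs, mitochondrial ribosomal RNA and small RNAs were chosen only after the result was seen. So were 4 further groups of genes, for which counts by edgeR's adjusted p are given as a description and no test of the group. Of 10 genes of HLA class II presentation tested, which include CIITA and CD74 besides HLA genes, 8 rose and 0 fell, with a median log2 fold change of 1.38. Of these 8, 6 belong to the B cell list and are counted there, CIITA, HLA-DRA and HLA-DPA1 among them, and of the 4 genes outside the lists fixed before the data were examined HLA-DMA and HLA-DMB rose. CD74, the class II chaperone, rose from 168 ± 20.1 to 336 ± 162 CPM (SD, n = 2). Of 18 class I presentation genes 8 rose and 1 fell (median 0.40), and 6 rose and 0 fell among the 13 outside those lists. TAP1, a peptide transporter, rose from 248 to 482 CPM and HLA-E from 343 to 523 CPM, while B2M was at 426 and 472 CPM and did not pass. Transcripts of the interferons were few: 22 interferon genes together had 52 and 51 counts in the control libraries and 104 and 150 in the LINC01432 LNA libraries. IFNL1 rose from 0.358 to 2.38 CPM and IFNB1 from 0.116 to 0.587 CPM, while IFNG, at 0.656 and 0.329 CPM, did not pass. Of 32 tested interferon and nucleic acid sensing genes 13 rose, among them the DNA sensors CGAS and AIM2 and the RNA sensors IFIH1 and RIGI, and 1 fell, MAVS (median 0.24); 11 of the 30 outside those lists rose. Of 23 immediate early genes 11 rose and 0 fell, 10 of them among the 20 outside those lists, with JUND, JUNB and EGR1 3.05-fold, 2.19-fold and 2.75-fold higher. After GC correction 8 of these genes rose and 2 fell, and the log2 fold changes of JUND, JUNB and EGR1 were 0.88, 0.70 and 1.42 instead of 1.61, 1.13 and 1.46, all called. Without control library 1 and without control library 2, HLA-DMA (log2 fold changes 0.59 and 0.72, against 0.67 with all libraries), HLA-DMB (1.26 and 1.87, against 1.57), IFNB1 (1.79 and 2.98, against 2.32), CGAS (0.34 and 0.37, against 0.37) and MAVS (-0.27 and -0.32, against -0.28) were not called. HLA-E was not called without control library 1 (0.53, against 0.61), nor IFNB1 without LINC01432 LNA library 1 (2.02). HLA-DMA (0.44) and HLA-DMB (1.37) were not called without LINC01432 LNA library 2 either, and CD74 and HLA-E were then called at 0.38 each, against 1.00 and 0.61. B2M was called as higher without LINC01432 LNA library 1 (0.31). DESeq2 did not call CD74 (0.98, adjusted p = 0.279) or HLA-DMA (0.64, adjusted p = 0.199).

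Long genes were lower: after GC correction the rank correlation of log2 fold change with gene body length was -0.17 across 13755 genes, which are not independent replicates, and the longest decile, from 148 kb, had 30 genes higher and 210 lower.

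GC-rich genes were higher in the LINC01432 LNA libraries; if libraries recovered GC-rich RNA differently, subunits of fixed complexes, whose genes tend to be expressed together, should show the same slope. Over 163 ribosomal protein, proteasome and oxidative phosphorylation genes the log2 fold change rose by 0.15 per 10 GC percent (95% interval 0.11 to 0.20), against 0.19 over all genes. The interval measures the scatter across genes, which are not independent replicates, and not the spread between libraries. The LINC01432 LNA libraries also differed from each other along GC (rho = 0.39 across genes), and the control pair less so (0.10). In the highest GC decile, however, both LINC01432 LNA libraries lay above the control mean, with medians of 0.30 and 0.44. They differed from each other there by a median of 0.15. The trend between these 2 libraries thus does not account for the rise that they share in that decile. Gene length as the source of the trend is argued against, since the correlation with GC stayed at 0.27 or more in each of 5 classes of body length, against 0.44 over all. A difference in GC recovery between libraries may account for some of this trend. An effect of the knockdown on GC-rich genes stays open, since group and library go together.

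Interferon and NF-kB genes were higher in the LINC01432 LNA libraries. The GC trend is argued against as the cause: the median of the 44 interferon genes with a mean above 1 CPM, 0.68, lay above those of all 10000 random lists matched on GC and expression, the highest of which was 0.047. No single library made the pattern, as the median of the interferon list was at least 0.61 without each library in turn. A response of the cells to the sequence of the LNA itself and a response to less LINC01432 cannot be told apart, because each group had 1 LNA design and no second design against LINC01432 was included. A second design, or LINC01432 restored by other means, would separate these hypotheses. The labels state neither the dose of the control LNA nor separate cultures. A difference of dose or culture between the groups therefore cannot be told apart from them either.

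The 5.8S ribosomal RNA genes were higher in both LINC01432 LNA libraries. Summed over 12 genes they were at 7.36 ± 3.96 CPM of library totals with control LNA (4.56 and 10.2 in libraries 1 and 2) and 729 ± 115 with LINC01432 LNA (810.0 and 648; SD, n = 2). Only 7 of the 12 held any counts. A copy on a sequence outside the assembled chromosomes held 14867 of 16907 counts in LINC01432 LNA library 1 and 15355 of 16969 in library 2. The copies are near-identical, so the counts do not show which of them changed. A loss of removal alike for ribosomal RNA of every kind is argued against: mitochondrial ribosomal RNA was at 94.9 and 16.2 CPM in the control libraries and 68.8 and 240 CPM in the LINC01432 LNA libraries, so that its ratio over pairs of libraries was 0.725 to 14.8, against at least 63.7 for 5.8S RNA. Better recovery of small RNAs in general is argued against as well, since 80 other RNAs under 200 bases had a median log2 fold change of 0.15 (95% interval 0.03 to 0.35). No rows of the longer cytosolic ribosomal RNAs were found by name, so those RNAs could not be compared. The rise is therefore not shown to be particular to 5.8S RNA. Poorer removal of cytosolic ribosomal RNA as a whole, poorer removal of 5.8S RNA alone, and a change of this RNA in the cells stay open and were not tested.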
